A study of Mus musculus with 8 samples.

How the data were processed

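Bulk RNA-seq libraries were made with the Smart-seq2 protocol, which reverse-transcribes polyadenylated RNA from small numbers of cells, amplifies full-length cDNA and fragments it with Tn5 transposase. Mouse haematopoietic stem cells (HSCs) were sorted into lysis buffer, per the labels' protocols. The labels name 4 libraries NTC, a non-target control, and 4 libraries miR652-KD. They do not say how miR-652 was knocked down, which markers defined the sort, the age of the mice or whether replicates came from separate animals. P-values therefore measure the spread between these libraries, which may be partly technical.

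The deposited files hold whole-number read counts per gene, not normalized. Per the submitters' processing notes the tools were HISAT2 2.1.0, HTSeq 0.11.2 and DESeq2 with the mm10 genome build; the annotation release and the strand setting are not given in the sources used here. Each file lists 55487 genes and 5 HTSeq summary lines. The summary lines were kept out of library sizes and tests. Reads outside annotated genes amounted to 9.69% to 16.94% as a share of the summed file, and ambiguous reads to 8.94% to 12.28%. Gene identifiers were matched without their version to the GENCODE M21 annotation of the same build, in which 55394 were found. The 93 others held at most 0.004% of the counts of any library. With this library protocol, reads of overlapping and antisense genes cannot be separated by strand. Counts of near-identical copies, such as the haemoglobin alpha genes Hba-a1 and Hba-a2, other haemoglobin genes, MHC genes and ribosomal protein genes with processed pseudogenes, are uncertain where reads could be split between them.

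Counts assigned to genes totalled 14.02 to 16.76 M in NTC and 14.68 to 19.89 M in miR652-KD, where M stands for the SI prefix mega. Smart-seq2 has no molecular identifiers, so amplified copies are counted as reads and counting intervals cover counting error only. The main test was edgeR 4.0.16 (R 4.3.3), with TMM scaling, genes kept by filterByExpr at its default minimum count of 10 and total of 15, robust quasi-likelihood fits and the quasi-likelihood F test of group. This left 14360 genes. P-values were adjusted by the Benjamini-Hochberg method and called below 0.05 with no minimum fold. CPM are counts per M of the TMM-scaled library size. Log2 fold changes are miR652-KD relative to NTC, and SE is the log2 fold change divided by the square root of F. The log2 CPM of library-level comparisons used a prior count of 2.

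A total of 33 gene lists, covering HSC identity and ageing, blood lineages and other cell types, the cell cycle, signalling, stress, metabolism, translation, the small RNA pathway and pseudouridine synthases, were written before the data were examined, as were the tests, the rule for named genes and all alternative settings but those named below as added. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with an estimated correlation and fry beside it. Reactome pathways from fgsea 1.28.0 with 15 to 500 tested members were treated likewise. Of their 7111 gene numbers, 6858 were matched to the annotation. For each arm of miR-652, the median log2 fold change of protein-coding genes with an 8mer or 7mer-m8 site in the longest annotated 3′ UTR was compared with that of genes without one. The difference was ranked among those of all other heptamers with the same bases and number of CpG as an exact two-sided rank p. Library-level values were compared with exact two-sided permutation tests over 70 splits, whose smallest possible p is 0.0286.

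Named genes were Tmem164, Mir652 and Pus10, then per direction the 10 protein-coding genes of largest fold change past the threshold. Those had a symbol other than Gm numbers or Rik names, a mean of at least 5 CPM in the higher group and no overlap between groups. Where fewer passed, genes of smallest p under the same conditions filled the places and are given as values that did not pass. For each list up to 4 members past the threshold were added, and for each list called by camera the 3 members of smallest p in its direction. Of these, 1 gene is not reported here.

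The procedures were tested on simulated counts for 14360 genes of the miR652-KD against NTC comparison. In these, 200 genes with a mean of at least 5 CPM were changed, and a further list of 40 such genes was raised by 0.6 log2. Of the 2-fold changes 28% were recovered, and of the 4-fold changes 68%, while 6 unchanged genes were called. Camera called 0 of 50 unchanged lists, which were simulated with independent genes. Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom with quality weights, no filter, a filter of 5 CPM in 4 libraries, non-robust fits, the replicate number as a block, 1 surrogate variable (sva 3.50.0), thinning to the smallest library, leaving out each library and other site definitions. Leaving out NTC replicates 3 and 4 together, and testing the macrophage and dendritic list without its class II genes, were added after the data had been seen.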

Results

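Gene expression was profiled in 8 bulk RNA-seq libraries of sorted mouse HSCs, the cells at the top of the blood lineage tree, 4 labelled NTC (non-target control) and 4 labelled miR652-KD. The series title concerns pseudouridine synthase 10 (Pus10) in aged HSCs, and the comparison asks which transcripts differ when the microRNA miR-652 is knocked down. NTC libraries held 15.1 ± 1.18 M counts in genes (SD, n = 4) and miR652-KD libraries 17.1 ± 2.17 M (SD, n = 4). At least 1 count was found for 17029 ± 539 genes in NTC and 17025 ± 239 in miR652-KD (SD, n = 4; exact permutation p = 0.971). The 50 most abundant genes took 15.9% ± 0.719 of counts in NTC and 15.9% ± 0.420 in miR652-KD (SD, n = 4; exact permutation p = 0.83).

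The targeted locus came first. Mir652 lies on chromosome X from 142739000 to 142739097 (mm10, plus strand), in an intron of Tmem164 (ENSMUSG00000047045.17, chromosome X, 142681406 to 142843494, plus strand), and overlaps none of its exons. Mature microRNAs are too short for this assay. The annotated hairpin had 1, 0, 0 and 2 counts in the NTC replicates 1 to 4 and 5, 0, 0 and 0 in those of miR652-KD. These few counts lie in an intron of the host gene and the knockdown method is not given, so the knockdown could not be checked with this assay. The host gene Tmem164 was at 102 ± 26.8 CPM in NTC and 70.1 ± 11.9 CPM in miR652-KD (SD, n = 4). Its log2 difference of -0.54 (SE 0.21) did not pass the threshold (edgeR quasi-likelihood, adjusted p = 0.803). Pus10 (ENSMUSG00000020280.12, chromosome 11, 23665674 to 23732876), which encodes a pseudouridine synthase, was at 27.7 ± 11.4 CPM in NTC and 34.5 ± 12.2 CPM in miR652-KD (SD, n = 4). The groups overlapped, with a log2 difference of 0.32 (SE 0.35, edgeR adjusted p = 0.995).

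The MHC class II genes H2-Aa and H2-Eb1 and the invariant chain gene Cd74 rose in the miR652-KD libraries. H2-Aa (ENSMUSG00000036594.15, chromosome 17, 34282744 to 34287823), the alpha chain of the I-A molecule, went from 258 ± 35.2 to 517 ± 35.7 CPM (SD, n = 4). H2-Eb1 (ENSMUSG00000060586.11, chromosome 17, 34305867 to 34316674), the beta chain of I-E, went from 105 ± 10.6 to 277 ± 59.9 CPM (SD, n = 4). Cd74 (ENSMUSG00000024610.15, chromosome 18, 60803848 to 60812652), the invariant chain that escorts class II molecules, went from 351 ± 63.2 to 810 ± 137 CPM (SD, n = 4). In each of these genes the 4 miR652-KD values lay above the 4 NTC values. Their log2 fold changes were 1.00 (SE 0.11), 1.40 (SE 0.16) and 1.21 (SE 0.16), with edgeR adjusted p of 0.0241, 0.0241 and 0.0476. H2-Ab1, the I-A beta chain, had a log2 difference of 0.72 without overlap but did not pass (adjusted p = 0.438). Other genes of the pathway did not pass and overlapped between groups, among them H2-DMa at 0.14, H2-DMb1 at 0.04 and the regulator Ciita at 0.80. The I-E alpha chain gene H2-Ea-ps had 1 count in miR652-KD replicate 4 and 0 in every other library. A rise of the I-E molecule is therefore not shown. The Reactome pathway MHC class II antigen presentation, with 76 tested genes, was not called (median 0.04, camera adjusted p = 0.211).

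The other 3 genes past the threshold were Senp1, Acss1 and Hnf4a. Senp1 (ENSMUSG00000033075.17, chromosome 15, 98038744 to 98093744), a SUMO protease, rose from 55.7 ± 9.38 to 144 ± 19.0 CPM (SD, n = 4), a log2 fold change of 1.37 (SE 0.16, adjusted p = 0.0241). Acss1 (ENSMUSG00000027452.11, chromosome 2, 150618105 to 150668500), a mitochondrial acetyl-CoA synthetase, fell from 34.1 ± 4.82 to 6.42 ± 1.23 CPM (SD, n = 4), a log2 fold change of -2.41 (SE 0.28, adjusted p = 0.0241). Hnf4a (ENSMUSG00000017950.16, chromosome 2, 163506808 to 163572910), a nuclear receptor best known from liver, had 717 counts over the NTC libraries and 1 count over the miR652-KD libraries. The ratio of scaled counts was 811, with a 95% exact binomial interval of 145 to 32090 for counting error only (adjusted p = 0.0241).

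**Figure D1:**
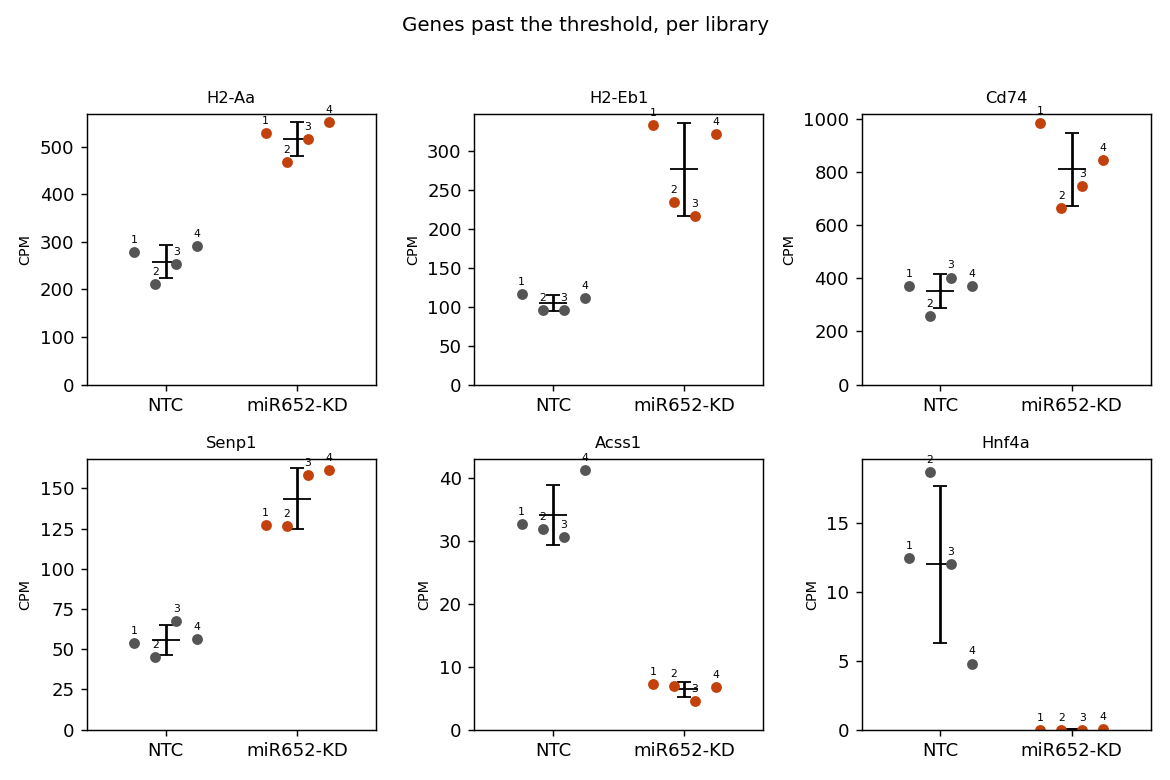
CPM of the 6 genes past the threshold in each library, with replicate numbers beside the points, the mean as a short line and bars for the SD (n = 4 per group). In each gene the 4 miR652-KD values lie apart from the 4 NTC values, and Hnf4a is near 0 in miR652-KD.

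In all, 6 of 14360 genes passed, 4 higher and 2 lower, and 860 had an unadjusted p below 0.05. The calls depended on having all 8 libraries. The groups did not overlap in these 6 genes, so leaving out libraries could hardly turn the direction, which is no check. Leaving out any single library left 0 genes past the threshold (789 to 992 at an unadjusted p below 0.05), as did leaving out NTC replicates 3 and 4. DESeq2 called 61 genes, 25 higher and 36 lower, and limma-voom 7. Leaving out single libraries, the log2 fold changes were 0.92 to 1.07 for H2-Aa, 1.30 to 1.5 for H2-Eb1, 1.09 to 1.30 for Cd74, 1.28 to 1.47 for Senp1 and -2.47 to -2.28 for Acss1. That of Hnf4a, near 0 counts in miR652-KD, moved more in size, from -10.57 to -8.71 (-9.06 with all libraries). The groups did not overlap for 4.39% of genes, against 2.86% expected by chance for 4 against 4.

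Among genes that did not pass, those of smallest p without overlap between groups had varied functions. Cd34, a surface antigen used to separate HSC subsets, was at 515 ± 13.7 CPM in NTC and 314 ± 42.5 CPM in miR652-KD (SD, n = 4), a log2 difference of -0.71 (edgeR adjusted p = 0.125). Cdk6, a cyclin D-dependent kinase, had a log2 difference of -0.51 (adjusted p = 0.377), and its partner Ccnd2 one of 0.42 (adjusted p = 0.438). On the higher side were also Ifitm3 at 0.41, Nt5dc2 at 1.34, Gem at 1.71 and the tRNA-processing enzyme Elac2 at 0.98. On the lower side were the Mediator subunit Med13l at -0.83, the Y-linked helicase Ddx3y at -1.02, Paqr5 at -1.16, the integrin Itgb3 at -0.92, the splicing kinase Clk1 at -0.48 and the mitochondrially encoded mt-Cytb at -0.36. Adjusted p of these 10 genes ran from 0.184 for Ifitm3 to 0.470 for mt-Cytb, Paqr5, Itgb3 and Clk1.

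Of the 33 gene lists, 12 were called by camera at the preset correlation, 9 higher and 3 lower. With an estimated correlation 0 were called, with 3 below an unadjusted p of 0.05 and a smallest adjusted p of 0.119, and fry called 0 in one direction. Camera called 7 lists without NTC replicate 4. The G2 and M phase list had the highest median. Of 45 tested G2 and M phase genes 40 had values above 0, with a median log2 difference of 0.61 (camera adjusted p = 1.43e-14; adjusted p = 0.451 with an estimated correlation). None passed over all genes. Adjusted over the list alone, 3 passed: Cdca8 of the chromosomal passenger complex (0.84), the cytokinesis protein Anln (1.33) and the spindle protein Ckap2l (1.16). Without miR652-KD replicate 3 the median was 0.36. List means overlapped between groups, at 5.45 log2 CPM in NTC replicate 3 against 5.23 and 5.40 in miR652-KD replicates 1 and 2. Of 38 S phase genes 29 were above 0, with a median of 0.19 (camera adjusted p = 0.00588; adjusted p = 0.553 with an estimated correlation). Adjusted over the list alone, 0 passed, with Pola1 at 0.77, Uhrf1 at 0.95 and Tyms at 0.56. That call was lost without NTC replicate 1 (adjusted p = 0.112), NTC replicate 4 (adjusted p = 0.301) or miR652-KD replicate 1 (adjusted p = 0.231), with medians of 0.12, 0.10 and 0.06, and without NTC replicates 3 and 4 together (median 0.05, adjusted p = 0.507). Without NTC replicate 2 the median was 0.35. That library had a list mean of 5.99 log2 CPM, above the 5.29 to 5.65 of miR652-KD replicates 2 to 4.

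Translation and respiratory gene lists called by camera had medians close to 0. Of 79 cytosolic ribosomal protein genes 77 were above 0, with a median of 0.17 (camera adjusted p = 3.24e-10; adjusted p = 0.455 with an estimated correlation). Rpl13 (0.23), Rplp1 (0.31) and Rps18 (0.22) had the smallest p, and 0 passed over all genes or adjusted over the list alone. Without NTC replicate 2 the median was 0.28. The groups overlapped in list mean: that library was highest of all 8, at 9.4492 log2 CPM against 9.2833 to 9.4475 in miR652-KD. Of 74 nuclear-encoded oxidative phosphorylation genes 61 were above 0, with a median of 0.13 (camera adjusted p = 3.86e-05; adjusted p = 0.455 with an estimated correlation). Ndufv1 (0.30), Ndufv2 (0.35) and Atp5d (0.27) led, 0 passed over all genes or adjusted over the list alone, and the call was lost without NTC replicate 1 (median 0.07, adjusted p = 0.116). Without NTC replicate 2 the median was 0.20. Here too that library had the highest list mean, at 7.4706 log2 CPM against 7.424 to 7.4666 in miR652-KD. The 12 tested mitochondrially encoded genes were all below 0, with a median of -0.30 (camera adjusted p = 8.69e-05; adjusted p = 0.455 with an estimated correlation). Adjusted over the list alone 5 passed, among them mt-Cytb (-0.36), mt-Co1 (-0.33) and mt-Nd4 (-0.32), and 0 over all genes. Mitochondrially encoded protein transcripts made up 2.39% ± 0.131 of counts in NTC and 1.88% ± 0.152 in miR652-KD (SD, n = 4), without overlap (exact permutation p = 0.0286, the smallest possible, and 0.114 after adjustment over 4 library measures).

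Immune and interferon genes formed a further set. Of 14 tested macrophage and dendritic genes 11 were above 0, with a median of 0.45 (camera adjusted p = 8.25e-12; adjusted p = 0.119 with an estimated correlation). The class II genes H2-Aa, H2-Eb1 and Cd74 were the 3 members past the threshold over all genes, and 6 passed adjusted over the list alone. The median was 0.81 without NTC replicate 4, 0.73 without miR652-KD replicate 2, 1.14 without NTC replicates 3 and 4 together and 0.25 without the 4 class II pathway genes, and NTC replicate 1 had the lowest list mean, at 3.60 log2 CPM against 5.09 to 6.04 in the others. Of 44 type I interferon response genes 32 were above 0, with a median of 0.21 (camera adjusted p = 0.000296; adjusted p = 0.119 with an estimated correlation). Ifitm3 (0.41) was the 1 member past adjusted over the list alone, with Psmb8 at 0.30 and Ifit3 at 2.60. The 18 MHC class I and antigen presentation genes had a median of 0.15, 12 of them above 0 (camera adjusted p = 0.0323; adjusted p = 0.455 with an estimated correlation), with Psmb8, H2-Q7 (0.28) and Psmb9 (0.28) in front and 0 past adjusted over the list alone. That call was lost without NTC replicate 2, 3 or 4 or miR652-KD replicate 1 or 2, with adjusted p from 0.0521 to 0.169; the median was 0.07 without NTC replicate 4 and 0.08 without miR652-KD replicate 1. It was also lost with the replicate number as a block (adjusted p = 0.0621) and without NTC replicates 3 and 4 together (adjusted p = 0.296). List means overlapped, at 8.51 log2 CPM in NTC replicate 1 against 8.47 and 8.42 in miR652-KD replicates 3 and 4.

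Of 12 tested pseudouridine synthase genes 11 were above 0, with a median of 0.31 (camera adjusted p = 0.00201; adjusted p = 0.119 with an estimated correlation). Pus7l (1.46), Pusl1 (0.77) and Rpusd4 (0.39) had the smallest p, and 0 passed over all genes or adjusted over the list alone. The call was lost without NTC replicate 4, with a median of 0.24, and without NTC replicates 3 and 4 together (median 0.17, adjusted p = 0.107). Of 22 cholesterol synthesis genes 17 were above 0, with a median of 0.20 (camera adjusted p = 0.0128; adjusted p = 0.455 with an estimated correlation). Mvd (1.74) and Sqle (0.47) were among the members of smallest p, with 0 past over all genes or adjusted over the list alone. The call was lost without NTC replicate 1 (adjusted p = 0.0651), NTC replicate 4 (adjusted p = 0.104) or miR652-KD replicate 2, with medians of 0.17, 0.23 and 0.22. Without miR652-KD replicate 1 the median was 0.12. List means overlapped, at 4.95 log2 CPM in NTC replicate 3 against 4.87 and 4.92 in miR652-KD replicates 3 and 4.

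**Figure D2:**
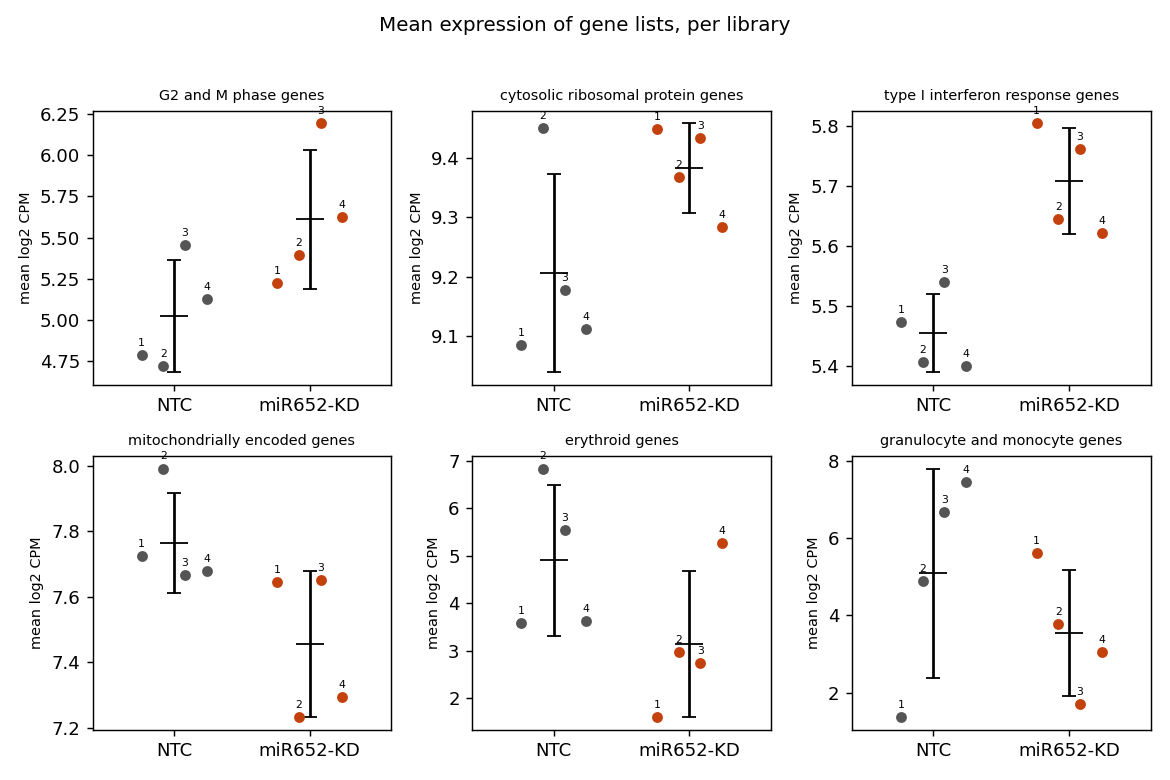
Mean log2 CPM of the tested members of 6 gene lists in each library, with replicate numbers beside the points, group means as short lines and bars for the SD (n = 4 per group). For G2 and M phase genes miR652-KD replicate 3 was highest at 6.19, and for granulocyte and monocyte genes the NTC replicates ranged from 1.36 to 7.44.

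The erythroid list and the granulocyte and monocyte list were called lower in miR652-KD, and both differed widely within groups. Of 22 tested erythroid genes 19 were below 0, with a median of -1.83 (camera adjusted p = 2.49e-06; adjusted p = 0.455 with an estimated correlation). Alas2, the erythroid enzyme of haem synthesis, was at 52.7 ± 7.40 CPM in NTC and 7.15 ± 7.40 CPM in miR652-KD (SD, n = 4), a log2 difference of -2.88, and was the 1 member past adjusted over the list alone. Hbb-bt (-2.68) and Hba-a2 (-2.89) followed. Hba-a1 ranged from 987 to 2634 CPM in NTC and stood at 2.21, 37.2, 65.3 and 1250.5 CPM in miR652-KD replicates 1 to 4. The median was -3.71 without miR652-KD replicate 4 and -0.56 without NTC replicate 2, which held Car1 at 396 CPM against at most 9.01 CPM in any other library. Of 26 granulocyte and monocyte genes 23 were below 0, with a median of -1.02 (camera adjusted p = 2.82e-05; adjusted p = 0.455 with an estimated correlation), and 0 passed adjusted over the list alone. Csf3r (-0.84) and Nkg7 (-0.83) were lower, but the neutrophil gene S100a9 was at 780 and 1192 CPM in NTC replicates 3 and 4 and at 2.1 to 11.6 CPM elsewhere. The call was lost without NTC replicate 4 (median -0.40, adjusted p = 0.201) or miR652-KD replicate 3 (median -0.68, adjusted p = 0.119), and the median was -2.73 without miR652-KD replicate 1. Without NTC replicates 3 and 4 together the median was 0.34 and S100a9 had a log2 difference of 1.75.

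**Figure D3:**
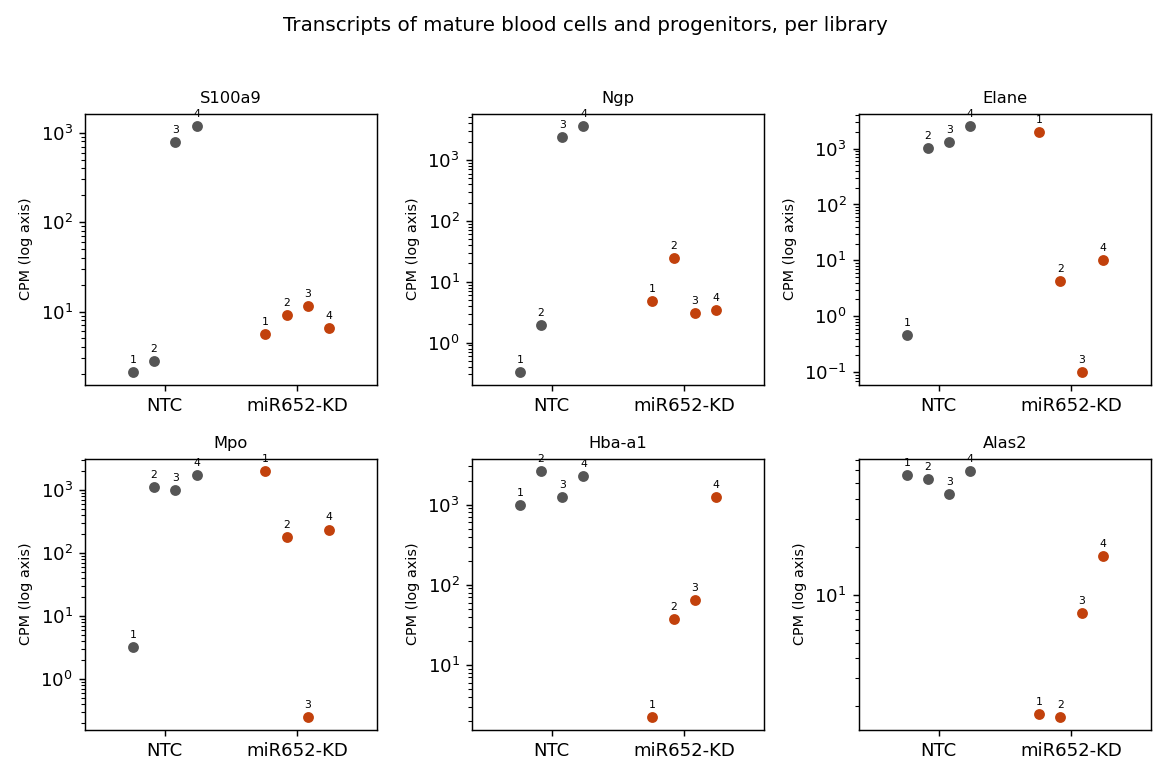
CPM on log axes of genes of neutrophils (S100a9, Ngp), myeloid progenitors (Elane, Mpo) and red cells (Hba-a1, Alas2) in each library, with replicate numbers beside the points. S100a9 and Ngp were high in NTC replicates 3 and 4, and Hba-a1 was low in miR652-KD replicates 1 to 3. Elane and Mpo were at 1948 and 2008 CPM in miR652-KD replicate 1 and at 0.46 and 3.28 CPM in NTC replicate 1. In replicates 2 to 4 they were at 1005 to 2547 and 1011 to 1727 CPM in NTC, and at 0.10 to 9.96 and 0.25 to 237 CPM in miR652-KD.

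HSC identity genes and genes known to rise in aged HSCs did not shift in a common direction. Of 40 HSC identity genes 21 were above 0 and 19 below, with a median of 0.03 (camera adjusted p = 0.191), and of 36 ageing genes 20 were above 0, with a median of 0.06 (adjusted p = 0.875). In fry's test for changes in either direction both lists passed (adjusted p = 0.000216 each), as did 14 of 33 lists. Adjusted over the list alone, Itgb3 of the ageing list passed, at -0.92. Among other cell types, camera gave adjusted p of 0.732 for megakaryocyte and platelet genes (median 0.01), 0.508 for lymphoid genes (median -0.05), 0.191 for mast cell and basophil genes (median -0.17) and 0.323 for endothelial and stromal genes (median -0.69, 6 tested). Cd74 was the 1 lymphoid-list member past the threshold. Ribosome biogenesis genes had a median of 0.12 (adjusted p = 0.0521), polyadenylated histone variants 0.08 (0.101), small RNA pathway genes -0.17 (0.121), heat shock genes 0.15 (0.16) and unfolded protein response genes 0.15 (0.191). Notch and Wnt genes had a median of -0.21 (adjusted p = 0.199), NF-kB and inflammatory genes -0.22 (0.423), quiescence genes -0.03 (0.485), CRL4 ligase genes -0.11 (0.508) and antioxidant genes 0.05 (0.678). Glycolysis genes had a median of 0.03 against a mean of -0.12 (adjusted p = 0.678), apoptosis genes 0.12 (0.692), p53 targets 0.09 against a mean of -0.02 (0.875), TGF-beta and BMP genes 0.02 (0.911) and immediate early genes -0.06 against a mean of 0.09 (0.926). The megakaryocyte list had a mean of -0.15 and the lymphoid list one of 0.04, opposite in sign to their medians; camera placed the TGF-beta list lower although its median and mean were above 0.

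Reactome pathways called by camera numbered 122 of 631, 122 higher and 0 lower, led by translation and mitosis. Eukaryotic Translation Elongation had a median of 0.17 over 90 genes (adjusted p = 5.68e-08), Mitotic Metaphase and Anaphase 0.13 over 160 genes (adjusted p = 0.000193) and DNA Replication 0.15 over 99 genes (adjusted p = 0.000452). With an estimated correlation 0 pathways were called, with adjusted p of at least 0.597. The count fell to 36 without NTC replicate 1 and to 55 with 1 surrogate variable.

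Loss of a microRNA is expected to raise transcripts that carry its seed sites, and neither arm's site genes passed the test after adjustment. For miR-652-3p, 230 genes with a 3′ UTR match to GCGCCAT had a median log2 difference of -0.04 against -0.01 for genes without one. The difference of -0.03 was equalled or exceeded by 79 of 239 control heptamers (exact rank p = 0.667). For miR-652-5p, 981 genes with TAGGGTT had a difference of -0.03, above the control median of -0.06 and exceeded by 1 of 139 control heptamers (exact rank p = 0.0286; 0.0571 adjusted over both arms). With 8mer sites alone the 5p exact rank p was 0.714. In simulated counts a shift of 0.3 log2 in every 3p site gene gave an exact rank p of 0.00833, the smallest this test can give. Smaller shifts were not simulated, so a smaller rise of site genes is not excluded.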

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

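All tests of explanations in this part were chosen after the results had been seen. Values far from the other 3 of their group, relative to the group's range, were found in 10 of 182 groups of 4 values, against 9.1 expected by chance at 1 in 20. NTC replicate 1 had 16.94% of reads outside annotated genes, against 10.39% to 11.35% in the other NTC libraries. In log2 CPM, miR652-KD replicate 3 was lowest for Acss1 at 2.24 and for Cd34 at 7.97, and miR652-KD replicate 4 held the single Hnf4a count of its group (-2.45). NTC replicate 3 was highest for Ckap2l at 4.00, miR652-KD replicate 1 lowest for Ndufv1 at 7.30 and miR652-KD replicate 2 highest for Rpusd4 at 5.89. Among list means, miR652-KD replicate 4 was highest for quiescence genes at 4.98, miR652-KD replicate 2 lowest for small RNA pathway genes at 5.96 and NTC replicate 4 lowest for pseudouridine synthase genes at 4.41.

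The 8 libraries can be split into groups of 4 in 35 ways. For the count of changed genes, 1 split, the real one, gave as many as the 6 found, and the highest other split gave 1. That share of 1 in 35 lies below 1 in 20, but without adjustment over the 4 results tested this way. These tests were also chosen after the results had been seen, so chance is not taken as excluded for that count. For called lists, 1 split, again the real one, gave as many as 12. For both counts 1 of 35 is the smallest share possible. Every other split also called lists, from 2 to 9, so camera at the preset correlation called lists in mixed groups too. The real split thus had the most lists, without adjustment over the 4 results. With an estimated correlation 0 lists were called, so chance is not excluded for single lists. For Reactome pathways 2 splits gave at least 122, the highest other giving 145, and chance cannot be excluded. For miR-652-3p site genes, 20 of the 35 splits lay at least as far from the control heptamers as the real 0.01, the highest other at 0.05, and chance cannot be excluded.

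H2-Aa, H2-Eb1, H2-Ab1 and Cd74 were higher in all 4 miR652-KD libraries than in any NTC library. Variation between strains in the H2 region on chromosome 17 is argued against as the whole cause by Cd74, on chromosome 18, at 1.21 (SE 0.16). RNA of B cells stays open: Cd79a and Cd79b together changed by -5.20 CPM (SE 10.7) while the 4 class II pathway genes gained 1127 CPM, but Ighm went from 6.74 to 35.6 CPM. RNA of macrophages or dendritic cells may contribute: the other tested members of that list had a median of 0.25. Their unadjusted camera p at an estimated correlation was 0.162, which keeps this open. For the whole list, class II genes included, the same p was 0.00468. Csf1r had 0 counts in each NTC library and 120, 52, 7 and 20 in miR652-KD replicates 1 to 4, and Cd68 went from 23.7 to 47.0 CPM, while C1qa was at 0.05, C1qb at -0.54, C1qc at -0.57 and Fcgr3 at -0.40 in log2; the markers of the sort are not given, and an effect of the knockdown itself on HSCs stays open as a hypothesis.

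The G2 and M phase list was called higher in miR652-KD by camera (adjusted p = 0.451 with an estimated correlation). A single library with more cycling cells could account for part of the shift, as the median was 0.36 without miR652-KD replicate 3. The unadjusted camera p at an estimated correlation was 0.0844 without that library and 0.0547 with all 8, and these values do not decide it. RNA of cycling erythroid or myeloid progenitors would raise erythroid, granulocyte and monocyte genes, which had a median of -1.18, but with p = 0.0639 at an estimated correlation this stays open too. A change of cell cycle state with the knockdown also remains open.

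The erythroid list and, with all 8 libraries, the granulocyte and monocyte list were called lower in miR652-KD by camera (adjusted p = 0.455 for each with an estimated correlation). Neutrophil RNA in NTC replicates 3 and 4, where S100a9 was at 780 and 1192 CPM, may contribute. The 21 granulocyte and monocyte genes other than neutrophil granule genes, however, had a median of -0.83. Their unadjusted camera p at an estimated correlation was 0.305, against 0.222 for the whole list, which leaves it open. For erythroid genes, red cell RNA carried into some libraries may play a part. Mean haemoglobin log2 CPM differed between groups (exact permutation p = 0.0286, the smallest possible), at 8.53 in miR652-KD replicate 4 against 8.56 to 10.01 in NTC. The other erythroid genes had a median of -1.14, so carried red cell RNA and a difference in erythroid genes of the HSCs cannot be told apart, and a biological effect of the knockdown stays untested.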

How the results depend on the processing

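Leaving out NTC replicates 3 and 4 together was chosen after the data had been seen. The count of 6 changed genes was 61 with DESeq2, 1 with 1 surrogate variable, 0 without NTC replicates 3 and 4 and 0 to 0 when any single library was left out, where fewer samples remain (884 genes had an unadjusted p below 0.05 without the pair). Leaving out single libraries, H2-Aa kept a log2 fold change of 0.92 to 1.07, Senp1 1.28 to 1.47 and Acss1 -2.47 to -2.28. Hnf4a ranged more widely, from -10.57 to -8.71. Other causes of the lost calls were not tested. The count was 5 to 7 under the other scalings, filters, limma-voom, non-robust fits and thinning. The labels do not say whether equal replicate numbers mark pairs. Deviations of same-numbered libraries correlated at -0.03 to -0.01, about the range of differently numbered ones (-0.03 to 0.05). These values show no sign of pairing but cannot exclude it. With the replicate block 0 genes passed (733 at an unadjusted p below 0.05), beside 11 lists and 116 pathways. Lists called were 0 with an estimated correlation, 0 with fry and 7 to 13 leaving out single libraries. Pathways were 55 with 1 surrogate variable and 36 to 158 leaving out single libraries; the cause was not tested. The 3p seed-site difference kept its sign and did not pass in 21 alternatives (-0.06 to -0.01). The 5p rank p, 0.0286, was above 0.05 in 9 of 19 alternatives (up to 0.40), 5 of them among the 8 that left out a single library. Tmem164 kept its sign and did not pass in 19 (-0.68 to -0.40). Pus10 was -0.0226 without NTC replicates 3 and 4 and did not pass in 19. The difference in detected genes was 51.0 at a minimum of 5 counts and -193.5 to 230.2 leaving out single libraries. The granulocyte list (0.34) and S100a9 (1.75) turned without NTC replicates 3 and 4. Camera's direction turned in some settings for an uncalled list: megakaryocyte and platelet genes (median 0.01), at 0.0619 with 1 surrogate variable and -0.21 to 0.10 leaving out single libraries, and for ageing genes, at -0.0337 to 0.16. Medians also crossed 0 without a turn of camera's direction for lymphoid (-0.31 to 0.15), HSC identity (-0.01 to 0.09) and mast cell genes (-0.21 to 0.04). In all, 2 of 986 alternative values of the 52 named genes turned in sign. Many of these genes were chosen for groups without overlap or for small p in a given direction, which makes turns unlikely. In simulation 28% of 2-fold changes were recovered, so such changes can be missed at this sample number. That simulation changed 200 genes of at least 5 CPM, far more than the 6 called here, so the share recovered in the real data may be lower.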

Other observations

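The genes below were chosen after their values had been seen, and none passed the threshold over all genes. Within the HSC identity list, Ly6a, which encodes the surface antigen Sca-1, was at 279 CPM in NTC and 427 CPM in miR652-KD, without overlap (log2 difference 0.62, SE 0.15, edgeR adjusted p = 0.598). Mllt3 and Mycn were also higher, at 0.60 and 0.46, while the receptor Kit was at -0.34 and the transcription factor Mecom at -0.33. In the ageing list Vwf and Aldh1a1 were at 0.53 and 0.48, and Plek and Itga6 at -1.02 and -0.56. The cell cycle inhibitor Cdkn1b was at -0.74 (SE 0.19), without overlap.

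The next 3 immune genes had low counts and overlapped between groups. Irf8, a transcription factor of myeloid and dendritic development, had a log2 difference of 2.22 (edgeR adjusted p = 0.779), and the immunoglobulin heavy chain gene Ighm one of 2.40 (adjusted p = 0.779). Ciita, the regulator of class II transcription, was at 0.80 (adjusted p = 0.999). Among Y-linked genes, Ddx3y was at -1.02 while Eif2s3y was at -0.21, Kdm5d at -0.15 and Uty at -0.51.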
